A study of Mus musculus with 75 samples.

How the data were processed

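The gene-level read counts deposited with the series were used as they are. According to the submitters' processing notes, reads were aligned with STAR 3.0.4 and counted with featureCounts 1.4.5 of the Subread package, whose version is not given. The genome build and the strandedness of the libraries are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. Reads shared between close paralogs, such as Mrgpra2a and Mrgpra2b, Wfdc17 and Wfdc18, the globin genes and the H2 genes, may be counted for either member. Each of the 2 tables, 1 per experiment, holds 41388 mouse gene IDs, of which 40340 are in the GENCODE M21 annotation that supplied symbols and coordinates. IDs outside it take 0.143% of the reads in experiment 1 and 0.113% in experiment 2. The experiment 1 table also has 3 entries that are not mouse genes, 2 human gene IDs and a human fusion gene that repeats the counts of the first. All columns were assigned to samples by title, and 0 columns stayed unassigned. The values are whole counts.

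The groups follow the labels. The genotypes are wild type (wt), Kmt2c f/+ with Vav-Cre (het) and Kmt2c f/f with Vav-Cre (ko), where f is a floxed allele and Vav-Cre a transgene that drives Cre recombinase in blood cells. The wt libraries carry no Vav-Cre label, so ko against wt and het against wt do not separate the loss of Kmt2c from the presence of Cre, while ko and het both carry it. Which exons are floxed is not given in the sources used here, and gene-level counts include exons outside the deleted part. Nothing in the labels says whether replicates are separate animals, so the p values measure the spread between libraries, which may be partly technical. The HSC libraries of experiment 2 have HPCs as their cell type entry but HSC in title, source name and description, and they were grouped as HSC.

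Each comparison was tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F tests. Genes were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM, and the fit was robust. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each population of each experiment had its own fit with all its groups, and 2 further fits, of all libraries of an experiment, gave the differences between populations and the comparisons of wt populations. Together these 8 fits gave 29 comparisons. Adjusted p values below are from edgeR unless another tool is named. Expression is given as CPM after TMM scaling within the fit, as mean ± SD, so that CPM of 1 gene differ slightly between a fit of 1 population and a fit of all. Log2 fold changes are given ± SE.

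The 27 gene lists, written before the data were examined, cover haematopoietic lineages, cell cycle, signalling, metabolism, stress and cell types that a sort could carry along. Each was tested in every comparison with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, which made 783 tests. Beside it stands the adjusted p of camera with a correlation estimated from the data. Counts of members that pass are given over all genes tested and adjusted over the list alone. Sets of up to 200 genes highest in each wt population of experiment 1 were tested in the same way in experiment 2.

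The genes named in the text follow a rule also fixed before the data were examined. It takes Kmt2c, up to 6 genes higher and 6 lower by size of the fold change, members of the fixed lists with the smallest p, and a panel of haematopoietic genes. Genes named by size are protein coding and called, have a mean of at least 5 CPM in the higher group and, except in tests of a difference between effects, have no overlap between the groups' libraries. Predicted genes, Xist, Y-linked genes and antigen receptor segments were left out. Sva, and any other gene that makes up a count of 5 or fewer, was named after its values were seen.

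The alternatives set before the data were seen were DESeq2 1.42.0, RLE scaling, no filter on low counts, the replicate number as a block, all libraries of an experiment in 1 fit, limma voom with sample weights, and each library left out in turn. Added after seeing the data were a covariate of Y-linked expression (Ddx3y, Eif2s3y, Kdm5d and Uty), fits without the libraries GMP het 1 and GMP ko 2, genotype and number together as a block across populations, and list tests without the library labelled HSC wt IL1 replicate 1. In experiment 1 only ko libraries, replicates 1 and 4 of each population, hold Xist but almost no Y-linked reads, so sex is partly confounded with ko. The Y-linked covariate was added for this, though several wt and het libraries hold both. Residuals of libraries sharing a replicate number correlated above 0.1 in each pair of the 4 HPC comparisons in experiment 2 (r across genes 0.18 to 0.74) and of wt HPC against HSC (0.14 to 0.43). Blocked values are given for gene counts and, in HPC of experiment 2, for most lists named.

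The pipeline was tried on simulated data with 200 genes changed. For HSC ko against wt it recovered 65 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, with 8 false calls among 13562 genes. For GMP it recovered 75 and 99 with 8 false calls, for IL-1 in wt HPC 40 and 97 with 8, and for IL-1 in wt HSC 37 and 97 with 1. The test of a different IL-1 response between genotypes recovered 7 and 82 in HSC, with 3 false calls, and 11 and 66 in HPC, with 2. DESeq2 recovered 78 and 98 in the first case with 31 false calls and made 29, 50 and 37 false calls in the next 3. Of 20 unchanged lists camera called 0, and it found the 1 list that was changed, but regrouped real libraries passed a median of 233 of the 783 list tests.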

Results

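The data are total-RNA read counts per gene from 75 libraries of sorted blood cell populations of 8-week-old mice, made with a Qiagen micro kit and a Clontech SMARTer-type kit. The series title links Kmt2c mutation to features of activated and of quiescent haematopoietic stem cells and to an advantage after chemotherapy. Kmt2c encodes a histone H3 lysine 4 methyltransferase. Experiment 1 holds 48 libraries of untreated cells, with 4 libraries for each of the genotypes wt, het and ko in each of 4 populations. The populations are labelled HSC, HPC, pGM (pre-granulocyte-monocyte) and GMP. Experiment 2 holds 27 libraries of HSC and HPC from wt and ko mice given PBS or interleukin 1 (IL-1, 0.5 µg per mouse for 3 days). It has 4 libraries per HSC group, except 3 for HSC wt IL1, and 3 per HPC group. Together these are 29 wt, 16 het and 30 ko libraries in 20 groups. Total counts ranged from 13.3 M to 20.8 M per library in experiment 1 (median 16.0 M) and from 18.6 M to 42.8 M in experiment 2 (median 32.7 M). RLE scaling in place of TMM shifted the median log2 change by at most -0.09 (wt pGM against HSC).

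Kmt2c (ENSMUSG00000038056, chromosome 5 from 25271798 to 25498783 on the minus strand) was lower in ko than in wt libraries of every population. In untreated HSC its level was 60.4 ± 10.2 CPM in wt, 41.8 ± 3.42 in het and 18.8 ± 2.7 in ko (SD, n = 4 each), a log2 change of -1.68 ± 0.17 in ko against wt (adjusted p = 3.15e-05). In HPC it was 42.9 ± 11.9, 33.7 ± 7.9 and 13.2 ± 1.68 CPM (-1.70 ± 0.23, adjusted p = 0.000657). In pGM it was 36.7 ± 2.61, 28.4 ± 9.53 and 10.8 ± 3.44 CPM (-1.77 ± 0.24, adjusted p = 0.000426). GMP had the lowest wt level of the 4 populations, 15.7 ± 3.59 CPM, with 10.1 ± 0.898 in het and 5.49 ± 2.41 in ko (-1.52 ± 0.29, adjusted p = 0.0309). In experiment 2 Kmt2c fell in ko HSC after PBS (-1.55 ± 0.30, 18.5 ± 5.15 against 54.3 ± 14.9 CPM, n = 4, adjusted p = 0.02), in ko HPC after PBS (-1.51 ± 0.28, 18.2 ± 4.71 against 52.1 ± 19.8 CPM, n = 3, adjusted p = 0.0435) and in ko HPC after IL-1 (-1.68 ± 0.28, 13.3 ± 0.815 against 42.6 ± 4.16 CPM, n = 3, adjusted p = 0.0295). Het against wt changes of -0.53, -0.35, -0.37 and -0.63 in HSC, HPC, pGM and GMP did not pass (adjusted p 0.807, 0.963, 0.79 and 0.973). The ko against wt change did not differ between HSC and HPC, pGM or GMP by the test of the difference (-0.02 ± 0.33, -0.11 ± 0.34 and 0.13 ± 0.34, adjusted p 1, 1 and 0.959). The GMP call ended without any of ko 1, ko 4, wt 1, wt 2 and wt 4 and with the Y-linked covariate (adjusted p up to 0.135). The HSC call after PBS ended without any of ko 1, ko 2, wt 1 and wt 2 (up to 0.1), and each of the HPC calls ended without any of 5 of the 6 libraries and with the Y-linked covariate (up to 0.196 after PBS, 0.152 after IL-1).

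**Figure D1:**
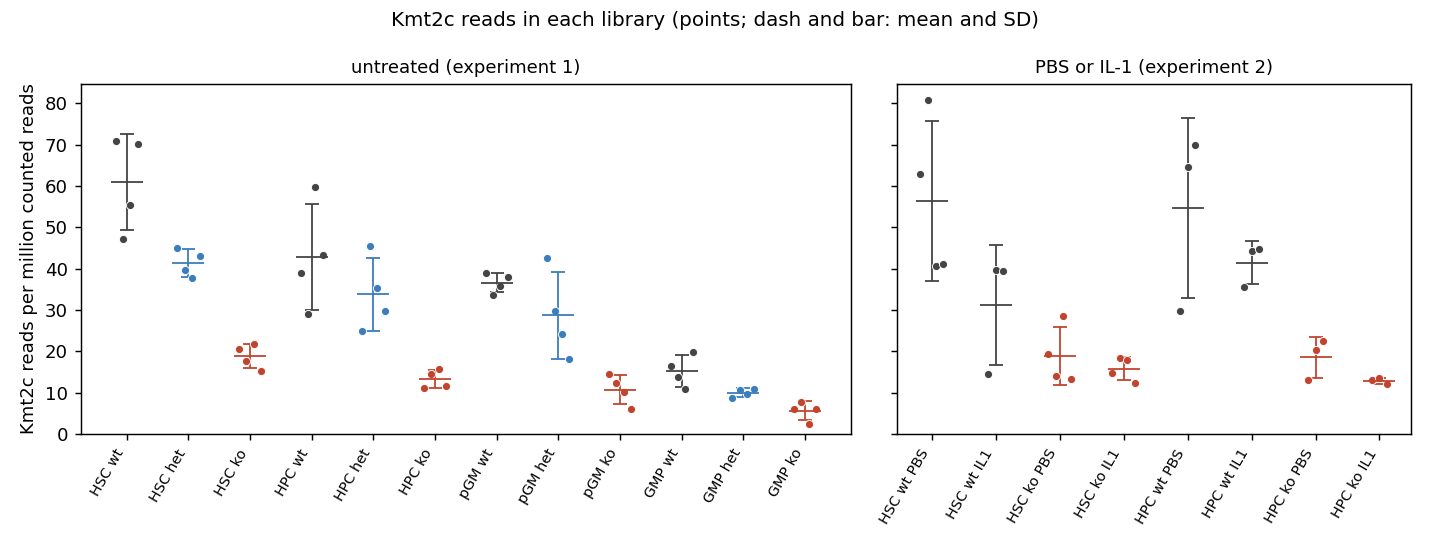
Kmt2c expression in CPM without TMM scaling (y axis), for each group of experiment 1 and of experiment 2 (x axis). Points are libraries, dashes are group means and bars are SD, and the ko groups lie below the wt groups of their population except that 1 library labelled HSC wt IL1 lies among the ko libraries.

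The library labelled HSC wt IL1 replicate 1 had 14.5 Kmt2c CPM without TMM scaling, against 39.7 and 39.5 in the others of its group. On an axis where the mean of HSC wt PBS is 0 and that of HSC ko PBS is 1, over 244 genes called in untreated HSC, it lay at 0.85. The other wt IL1 libraries lay at -0.21 and -0.10, and the ko IL1 libraries between 0.76 and 0.88. It was kept as labelled, bears on every result of HSC given IL-1, and values without it are given for the gene counts and for part of the genes, lists and sets. In those values the wt IL1 group is replicates 2 and 3 alone.

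**Figure D2:**
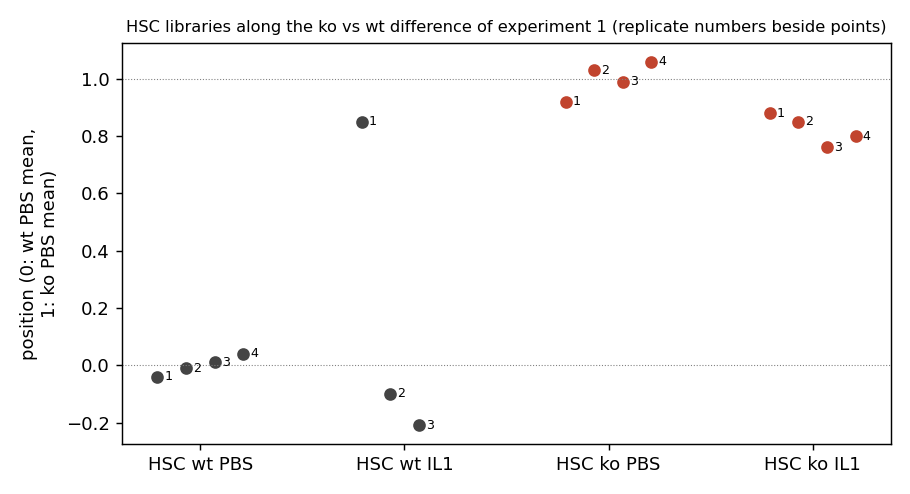
Position of each HSC library of experiment 2 (y axis, 0 is the mean of wt PBS and 1 the mean of ko PBS) along the genes called in untreated HSC of experiment 1, by group (x axis), with points for libraries and replicate numbers beside them. The library labelled HSC wt IL1 replicate 1 lies at 0.85, and the wt PBS libraries lie between -0.04 and 0.04.

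In the wt libraries of experiment 1, Slamf1, a surface receptor used to sort stem cells, fell from 35.8 ± 5.88 CPM in HSC to 1.07 ± 1.59 in HPC and 1.28 ± 1.82 in pGM (SD, n = 4). Mecom fell 4.09-fold in HPC and 12.3-fold in pGM, and Hlf 6.23-fold in pGM and 47.8-fold in GMP, both transcription factors of stem cells. Cd48, which stem cells lack on their surface, rose 34.2-fold in HPC to 409 ± 76.5 CPM and 51.1-fold in pGM. Of 25 lymphoid-primed genes, 18 rose and 2 fell in HPC, and 20 rose and 3 fell in pGM (camera adjusted p with an estimated correlation 0.000867 and 0.0115). In HPC, Dntt, the polymerase that adds nucleotides to antigen receptor joints, rose from 3.08 ± 1.11 to 1680 ± 342 CPM, Flt3 rose 12-fold, and Il7r stood at 12.2 ± 3.82 CPM against 0.0143 ± 0.0285 in HSC, while Gata3 fell (-1.27 ± 0.30, adjusted p = 0.0012). The receptor Il1r1 rose 8.32-fold in HPC and 3.69-fold in pGM and fell 3.01-fold in GMP. Kmt2c itself fell in wt GMP against HSC (-1.37 ± 0.24, adjusted p = 4.85e-06) and did not pass in HPC or pGM (-0.36 and -0.46, adjusted p 0.295 and 0.118). The fold changes named without a p had an adjusted p of 0.000132 or less.

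Of 30 HSC-associated genes, 29 fell in wt HPC and 30 in both pGM and GMP (camera adjusted p with an estimated correlation 1.31e-05, 7.91e-05 and 0.00107). Of 30 mitosis genes, 29 rose in HPC and 30 in pGM and GMP (likewise 0.0247, 0.0285 and 0.0702). Granulocyte-monocyte genes rose in 12, 24 and 29 of 30 cases (0.205, 0.0115 and 0.00459). Megakaryocyte-platelet genes fell in 16, 17 and 20 of 21 cases (0.00034, 0.0115 and 0.00459). In all, 1892 genes were higher and 1548 lower in HPC than in HSC, 3131 and 3121 in pGM, and 4162 and 5088 in GMP. RLE scaling turned the balance in HPC (1559 and 1751) and gave 2638 and 3576 in pGM. The replicate number as a block gave 747 and 605 in HPC, genotype and number 2082 and 1644.

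Untreated ko and wt HSC differed in 246 of 13806 genes, 79 higher and 167 lower in ko. Gpx8, a peroxidase of the endoplasmic reticulum, rose 10.7-fold from 1.84 ± 0.283 to 19.8 ± 3.14 CPM (SD, n = 4 per group, log2 3.42 ± 0.31, adjusted p = 7.86e-06). Fkbp10, a folding enzyme for collagen, rose 4.39-fold to 45.6 ± 13.1 CPM, and the tetraspanins Tspan12 and Tspan7 rose 4.58-fold and 4.31-fold. Armh4 rose 5.62-fold and the microtubule protein Map1b 5.2-fold. Rgs7bp, which anchors regulators of G protein signalling, fell 17.4-fold from 16 ± 2.64 to 0.914 ± 0.214 CPM (-4.12 ± 0.28, adjusted p = 1.96e-07). Fam198b fell 30.7-fold, the tight junction gene Cldn10 16.2-fold, Adgre4 15.3-fold and the histone deacetylase Hdac9 11.9-fold. Phldb2 stood at 0.0843 ± 0.169 CPM in ko and 8.7 ± 0.611 in wt. The 12 genes named so far had adjusted p of 0.0075 or less. In 1 fit of all libraries of the experiment, 37 genes were higher and 163 lower, and Armh4, Map1b, Tspan12, Tspan7 and Fkbp10 did not pass (adjusted p 0.0543 to 0.203). DESeq2 called 469 genes and limma voom 448, while 151 passed without ko replicate 1 and 153 without wt replicate 4.

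Platelet genes formed the clearest group in HSC. Of 21 megakaryocyte-platelet genes, 6 fell and 0 rose (9 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.12e-07 and 0.00483 with an estimated correlation). Multimerin 1 (Mmrn1), a platelet granule protein, fell from 308 ± 55.4 to 121 ± 46.6 CPM (-1.35 ± 0.23, adjusted p = 0.00357). The integrin Itga2b fell 2.18-fold and the glycoproteins Gp9 and Gp5 1.95-fold and 11.3-fold. Hemgn, a nuclear protein of blood progenitors and the only one of the erythroid list to pass in HSC, fell 4.39-fold to 12.3 ± 0.737 CPM (adjusted p = 2e-06). Genes of stroma and endothelium fell in 2 of 8 cases (4 adjusted over the list alone, 1.98e-06, 0.0254 with an estimated correlation), the proteoglycan gene Bgn by 3.29-fold from 169 ± 26.6 CPM and Kdr by 5.06-fold. Macrophage and mast cell genes fell in 3 of 13 cases (6 adjusted over the list alone, 5.41e-07, 0.136 with an estimated correlation). These were haem oxygenase Hmox1, 6.37-fold lower, the haemoglobin scavenger receptor Cd163, 2.26-fold lower, and the complement gene C1qb, 3.73-fold lower. Of 14 MHC class II genes 0 passed (3 lower adjusted over the list alone, camera adjusted p = 0.000216, 0.197 with an estimated correlation).

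In HSC Il1r1, the signalling receptor for IL-1, fell 3.35-fold from 8.37 ± 0.292 to 2.49 ± 0.599 CPM (-1.75 ± 0.28, adjusted p = 0.00192). The lymphoid factor Gata3 fell from 101 ± 15.1 to 54.5 ± 11 CPM (adjusted p = 0.00728) and the cytotoxic granule gene Nkg7 from 129 ± 21.3 to 69.8 ± 17.5 (0.0404). Among 20 cell cycle brakes, Txnip fell 1.68-fold from 1220 ± 115 CPM and the CDK inhibitor Cdkn2c rose 2.09-fold to 19.7 ± 2.73 (adjusted p 0.00434 and 0.00906). That list fell by camera (0.0486, 0.664 with an estimated correlation). Asparagine synthetase Asns, of the unfolded protein and integrated stress list, rose 2.01-fold to 209 ± 27.6 CPM (adjusted p = 0.00614), and 1 of 22 members of that list passed (2 adjusted over the list alone, 0.0486, 0.262 with an estimated correlation). Nr4a1, an immediate early gene, rose 2.18-fold to 20.4 ± 5.92 CPM (0.0359). The calls of Nr4a1, Nkg7, Kdr, Cd163 and C1qb ended in 7 to 10 of 15 alternatives each, among them leaving out any of 5 to 7 of the 8 libraries, with adjusted p up to 0.302, 0.157, 0.208, 0.143 and 0.224. Those of Gata3 and Gp9 ended in the fit of all libraries (0.17 and 0.0874).

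In ko HPC, Mmrn1 fell 37.6-fold from 33.4 ± 13.4 to 0.877 ± 0.201 CPM (SD, n = 4 per group, log2 -5.23 ± 0.35, adjusted p = 3.64e-07). The sphingosine phosphate receptor S1pr1 fell 10.7-fold to 2.4 ± 1.2 CPM, the lipid receptor P2ry10 8.28-fold, Wfdc2 14.1-fold, prostaglandin D synthase Hpgds 7.18-fold and the integrin Itga9 7.15-fold. Higher were Tcf7, a transcription factor of T cells, 6.23-fold to 7.97 ± 1.93 CPM, the transporter Slc6a15, 5.24-fold, the phosphatase Ptprf, 4.05-fold, Ms4a4c, 3.53-fold, and the collagen chaperone Serpinh1, 3.4-fold to 48.7 ± 3.75 CPM. Of 13276 genes, 33 were higher and 113 lower. DESeq2 called 302, limma voom 286 and the fit with the Y-linked covariate 36. Without ko 3, ko 4, wt 1, wt 2, wt 3 or wt 4 the count was 90, 86, 80, 94, 85 and 92.

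In ko HPC 2 of 30 granulocyte-monocyte genes rose (9 adjusted over the list alone, camera adjusted p = 1.83e-11, 0.0167 with an estimated correlation). These were proteinase 3 (Prtn3), from 670 ± 62.5 to 1240 ± 98.1 CPM (0.89 ± 0.15, adjusted p = 0.00559), and Ly86, from 7.59 ± 2.18 to 21 ± 8.22 (1.47 ± 0.33, 0.0374). Gata3 fell 6.58-fold to 5.8 ± 2.09 CPM (adjusted p = 8.94e-06), the thymus homing receptor Ccr9 6.88-fold to 7.5 ± 1.29, the T cell kinase Lck 1.99-fold and Nkg7 1.89-fold. In the lymphoid-primed list, 1 of 25 genes rose and 2 fell (camera adjusted p = 0.316). Of 18 megakaryocyte-platelet genes 3 fell and 1 rose (8 and 2 adjusted over the list alone, 8.03e-06, 0.0824 with an estimated correlation), with platelet factor 4 (Pf4) 5.05-fold and the thrombin receptor F2rl2 3.31-fold lower and P-selectin (Selp) 2.35-fold higher at 38.2 ± 6.75 CPM. Hemgn fell 4.31-fold and carbonic anhydrase Car2 from 5050 ± 625 to 2610 ± 611 CPM (adjusted p 0.00024 and 0.00704). Il1r1 fell 1.77-fold from 63.4 ± 6.84 to 35.7 ± 3.94 CPM (-0.83 ± 0.16, adjusted p = 0.0139), Procr 1.99-fold, Bgn 4.03-fold and the MHC class II gene H2-Ob 1.61-fold. That last list had 1 of 14 members lower (2 adjusted over the list alone, 0.0248, 0.773 with an estimated correlation). Asns rose 2.19-fold to 106 ± 17.3 CPM, 1 of 22 genes of its list (2 adjusted over the list alone, 0.0079, 0.38 with an estimated correlation), and spermidine synthase Srm 1.85-fold. Calls of Ms4a4c, Hpgds, Itga9, Procr, Ly86, F2rl2, Selp, H2-Ob, Srm and Il1r1 ended in 5 to 10 of 15 alternatives, among them leaving out any of 3 to 7 of the 8 libraries (highest adjusted p 0.165, 0.152, 0.246, 0.199, 0.322, 0.2, 0.223, 0.253, 0.192 and 0.279). The Ptprf call ended without ko 4 or wt 4 and that of Tcf7 without wt 1 (up to 0.117 and 0.0889 over all alternatives), and with the Y-linked covariate those of Car2, Pf4, Nkg7, Lck, Asns and Bgn ended as well (0.0562 to 0.108).

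In ko pGM, Mmrn1 fell 17.5-fold from 9.57 ± 3.7 to 0.534 ± 0.318 CPM (SD, n = 4 per group, -4.13 ± 0.47, adjusted p = 9.29e-05). Lower too were P2ry10, 13.1-fold, the ubiquitin ligase Rnf150, 12.8-fold, the mast cell adaptor Clnk, 12.2-fold, the mast cell protease Prss34, 11.8-fold, and Ccr9, 8.94-fold. Collagen gene Col5a1 rose 10.4-fold to 5.54 ± 1.98 CPM (3.38 ± 0.44, adjusted p = 0.000295), the carboxylesterase Ces2g 3.62-fold to 72.9 ± 24.5 CPM, Gdpd1 3.03-fold, the pyrin gene Mefv 2.89-fold and Ecm1 2.74-fold. Of 12939 genes, 53 were higher and 198 lower. DESeq2 called 421 and the fit with the Y-linked covariate 128, and 160 passed without wt replicate 1.

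By list, macrophage and mast cell genes fell in 3 of 16 cases in pGM (5 adjusted over the list alone, camera adjusted p = 3.21e-08, 0.0888 with an estimated correlation). Mast cell carboxypeptidase Cpa3 fell from 463 ± 64.3 to 155 ± 40.8 CPM (-1.57 ± 0.16, adjusted p = 8e-05) and the basophil protease Mcpt8 1.59-fold. Lymphoid-primed genes fell in 3 of 25 cases (5 adjusted over the list alone, 1.71e-05, 0.399 with an estimated correlation), with Dntt down from 741 ± 65.9 to 288 ± 67.6 CPM (-1.36 ± 0.16, adjusted p = 0.000136) and Gata3 3.58-fold lower. Of 9 mature lymphocyte genes 2 fell and 1 rose (3 and 1 adjusted over the list alone, 0.000214, 0.169 with an estimated correlation). Lck fell 2.65-fold to 24.4 ± 6.53 CPM, Nkg7 1.81-fold to 501 ± 65.1, and Cd4 rose 2.18-fold to 15.2 ± 5.49. Megakaryocyte-platelet genes went both ways, with 5 of 17 lower and 1 higher (the same counts adjusted over the list alone, 0.000199, 0.536 with an estimated correlation). Integrin Itgb3 fell 2.53-fold, and Selp rose 2.55-fold to 64.3 ± 11.7 CPM. Of 23 erythroid genes Car2 and Hemgn fell, 2.04-fold and 2.41-fold, and the factor Gata1 rose 1.74-fold to 115 ± 28.1 CPM (5 higher and 2 lower adjusted over the list alone, 0.0218, 0.648 with an estimated correlation). Il1r1 fell 3.16-fold from 25.8 ± 5.71 to 8.16 ± 1.2 CPM (-1.66 ± 0.20, adjusted p = 0.000159). Granulocyte-monocyte genes rose as a list (camera adjusted p = 0.00975, 0.648). Calls of Prss34, Cd4, Mcpt8 and Mefv ended in 8 to 12 of 15 alternatives (adjusted p up to 0.143, 0.14, 0.833 and 0.524). The Ccr9 call ended without ko 4 (up to 0.0916 over all alternatives). Col5a1 and Gata1 did not pass in the fit of all libraries (0.347 and 0.964), nor did Hemgn, Itgb3 and Gata3 with the Y-linked covariate (0.134, 0.0707 and 0.143).

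In GMP, the receptor gene Gpr141 fell 8.73-fold from 35.2 ± 5.68 to 4.05 ± 1.4 CPM (SD, n = 4 per group, -3.13 ± 0.26, adjusted p = 2.79e-05). S100a9, a granule protein of neutrophils, fell 7.49-fold from 94.5 ± 52 CPM, Cd180 6.86-fold, the IL-18 receptor chain Il18rap 6.64-fold, Nrp1 5.35-fold and Degs2 4.3-fold. Cathepsin F (Ctsf) rose 3.91-fold to 19.2 ± 2.62 CPM, eosinophil major basic protein Prg2 3.15-fold to 1710 ± 909, Cyp11a1 2.96-fold, Maged1 2.95-fold, Epsti1 2.32-fold and Hoxa9 2.23-fold to 15.3 ± 1.96. HSC-associated genes rose as a group, 4 of 17 (5 adjusted over the list alone, camera adjusted p = 1.17e-07, 0.0215 with an estimated correlation). Among them were Hoxa9, Gata2 at 27.6 ± 6.54 against 13.7 ± 1.3 CPM (1.01 ± 0.18, adjusted p = 0.0245) and Meis1 at 51.3 ± 8.27 against 28.5 ± 3.69 (0.85 ± 0.17, 0.0365). Cd27 rose 1.89-fold to 103 ± 8.08 CPM, and the platelet genes Plek and Itgb3 fell 2.73-fold and 3.72-fold, 2 of 11 of their list (camera adjusted p = 0.12). Mitosis genes had 0 of 30 past the test (2 lower adjusted over the list alone, 1.17e-07, 0.191 with an estimated correlation). Interferon-stimulated genes had 0 of 30 (4 higher adjusted over the list alone, 5.55e-06, 0.191), and mature neutrophil genes had 1 of 14 lower (3 adjusted over the list alone, 3.83e-05, 0.191).

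Of 12082 genes tested in GMP, 24 were higher and 43 lower. The balance depended on the method, with 116 and 109 by DESeq2, 112 and 117 by limma voom, 134 and 63 in the fit of all libraries and 87 and 107 without GMP het 1 and GMP ko 2, and 12 genes passed with the Y-linked covariate and 43 with the replicate block. GMP ko 2 stands apart from its group in mitochondrially encoded and ribosomal protein genes (1.51 and 0.92 log2 units), and no list was tested without both libraries. Leaving out ko 1, ko 3, ko 4, wt 1, wt 2, wt 3 or wt 4 left 21, 39, 25, 17, 16, 30 and 22 calls. Of the genes named in GMP, Cd180, Il18rap and Plek held in each alternative, and Gpr141 in all but the fit of all libraries (adjusted p = 0.0807). The others lost their call in 4 to 10 of 16 alternatives, among them leaving out any of 2 to 8 of the 8 libraries, with adjusted p of up to 0.115 for Hoxa9, 0.0935 for Gata2, 0.164 for Meis1, 0.071 for Ctsf, 0.736 for Prg2 and 0.561 for S100a9. Cyp11a1, Maged1, Epsti1, Nrp1, Degs2, Itgb3 and Cd27 reached 0.11, 0.115, 0.192, 0.199, 0.281, 0.179 and 0.115.

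**Figure D3:**
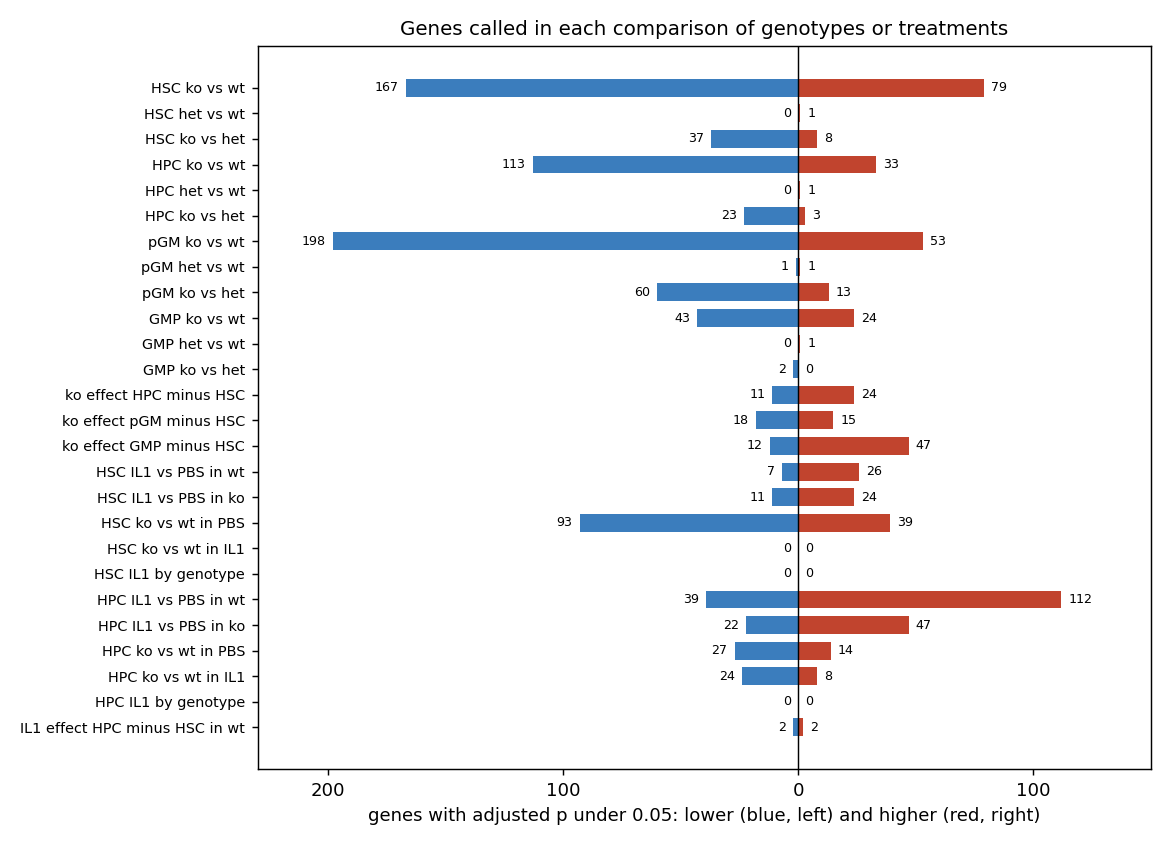
Number of genes called by edgeR at an adjusted p under 0.05 (x axis, genes higher to the right and genes lower to the left) in each comparison (y axis) except those between wt populations. Ko against wt gave 246, 146, 251 and 67 genes in untreated HSC, HPC, pGM and GMP, and het against wt gave 1, 1, 2 and 1.

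Heterozygous libraries differed from wt in 1 gene in HSC, HPC and GMP and in 2 in pGM. Sva (ENSMUSG00000023289, chromosome 6 from 42038394 to 42042851 on the plus strand), known as a seminal vesicle protein, was the gene higher in all 4 populations (edgeR adjusted p 0.00668, 0.0197, 0.0189 and 0.022). Over both experiments the 46 libraries with a Vav-Cre label held 15 to 77 Sva reads with a median of 27. The 28 wt libraries other than HSC wt IL1 replicate 1 held 0 to 3, 26 of them 0, and that library held 59. Ko did not differ from het in Sva (-0.28 ± 0.50, 0.29 ± 0.53, -0.10 ± 0.53 and 0.25 ± 0.45, adjusted p 0.946, 0.99, 0.987 and 0.998). In pGM the zinc transporter gene Slc39a1 fell from 134 ± 20.9 to 70 ± 10.6 CPM (SD, n = 4, -0.94 ± 0.14, adjusted p = 0.0189), and its call ended without any of the 4 het libraries, wt 1 or wt 3 and in the fit of all libraries (up to 0.894). Sva lost its call without HPC het 2 or any HPC wt library, without pGM het 1, 2 or 4 or pGM wt 1 or 3, and without any of the 8 GMP libraries (up to 0.225, 0.136 and 0.219 over all alternatives). With the replicate block it lost its call in HSC (0.113), HPC and GMP. At unadjusted p under 0.05, het against wt had 758, 560, 951 and 336 genes (690, 664, 647 and 604 by chance), and DESeq2 called 20, 13, 58 and 1.

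Het and ko changes use the same wt libraries, which alone makes them covary. Across all genes tested, which are not independent replicates, the covariance in HSC, HPC, pGM and GMP was 0.142, 0.136, 0.0948 and 0.108, against 0.0848, 0.0838, 0.0591 and 0.0611 simulated with shared controls and no effect. The differences were 0.0576 (jackknife SE 0.0173), 0.0526 (0.0233), 0.0356 (0.0149) and 0.0473 (0.0388). At a mean CPM of at least 10 they were 0.0117, 0.0349, 0.00835 and 0.0147, and without GMP het 1 that of GMP was 0.0196. With separate wt libraries for each, the covariance was 0.0709, 0.0775, 0.0373 and 0.065.

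Ko against het compares genotypes that both carry Vav-Cre, and it changed 45 genes in HSC, 26 in HPC, 73 in pGM and 2 in GMP. In HSC 8 rose and 37 fell. Higher were Gpx8, 3-fold to 19.8 ± 3.14 CPM (SD, n = 4 per group, 1.59 ± 0.28, adjusted p = 0.0148), Ramp2 2.85-fold, Tspan12 2.82-fold, the aminopeptidase Anpep 2.63-fold, Cd38 2.21-fold and Serpinh1 2.15-fold to 68.1 ± 10.7. Rgs7bp fell 9.65-fold (adjusted p = 7.43e-06), Hdac9 6.63-fold, the adaptor Fyb 4.96-fold to 5.77 ± 1.05 CPM, S1pr1 4.81-fold, Il18rap 4.71-fold and Cd96 4.16-fold. Hemgn fell 2.71-fold (0.000534), Bgn 2.39-fold and Gp5 7.09-fold. Platelet genes had 1 of 21 lower (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00141, 0.0967 with an estimated correlation) and stroma genes 1 of 8 (2 adjusted over the list alone, 0.000443, 0.105). The calls of Ramp2, Anpep and Gp5 ended in 10 or 11 of 15 alternatives, among them leaving out any of 7 of the 8 libraries (up to 0.404, 0.241 and 0.258). Gpx8 did not pass without het 2, het 3 or ko 1, nor Cd38 without het 1, het 3 or ko 2 (up to 0.704 and 0.539 over all alternatives), and DESeq2 called 136 genes, the fit with the Y-linked covariate 22, and 29 passed without het replicate 3. The fit of all libraries gave 2 higher and 59 lower, and none of the genes named as higher passed in it, nor did Bgn (Tspan12, Serpinh1 and Bgn 0.714, 0.204 and 0.148). Cd96 and Il18rap did not pass with the Y-linked covariate (0.0644 and 0.0667).

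In HPC, ko against het had 3 genes higher and 23 lower. Mmrn1 fell 17.6-fold from 15.6 ± 4.9 CPM (SD, n = 4, -4.14 ± 0.34, adjusted p = 9.53e-06), P2ry10 6.02-fold, S1pr1 5.88-fold, Pdcd1lg2 4.79-fold, Gcsam 4.49-fold, Ccr9 4.12-fold, Gata3 2.8-fold, Hemgn 2.69-fold and Il1r1 1.89-fold. The lectin gene Lgals1 rose 2.22-fold to 580 ± 112 CPM (0.00604), Ms4a4c 3.71-fold and Cyp27a1 2.45-fold. The granulocyte-monocyte list rose with 0 of 30 members past the test (4 adjusted over the list alone, camera adjusted p = 1.53e-08, 0.0472 with an estimated correlation). With the Y-linked covariate 2 genes passed, with the replicate block 13, in the fit of all libraries 12 higher and 34 lower, by DESeq2 111, and without ko 1, ko 3 or ko 4 12, 11 and 13. Kmt2c (-1.35 ± 0.23, adjusted p = 0.0175) and Hemgn, Il1r1, P2ry10, Pdcd1lg2, Ms4a4c and Cyp27a1 lost their calls in 6 to 10 of 15 alternatives, among them leaving out any of 4 to 7 of the 8 libraries (up to 0.325, 0.309, 0.411, 0.162, 0.592, 0.598 and 0.445), and Gata3 did without ko 1 or ko 3 and with the Y-linked covariate (up to 0.0699). S1pr1 lost its call with the replicate block and the Y-linked covariate (up to 0.076), and Lgals1, Gcsam and Ccr9 with the latter (0.133 each).

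In pGM, ko against het had 13 genes higher and 60 lower. The erythroid factor Klf1 rose 4.3-fold to 12.4 ± 4.39 CPM (SD, n = 4, 2.10 ± 0.41, adjusted p = 0.0249), the cytokine Tslp 2.1-fold, Wtap 1.86-fold, the CDK inhibitor Cdkn1b 1.68-fold and Slc39a1 1.68-fold. Cd96 fell 4.34-fold to 4.38 ± 1.46 CPM (-2.12 ± 0.21, 8.95e-05), Clnk 7.08-fold, Tnip3 4.78-fold, the transcription cofactor Eya2 4.74-fold, Cpa3 2.43-fold, Dntt 2.09-fold, Lck 2.18-fold, Nkg7 1.74-fold, Il1r1 2.36-fold and Mmrn1 5.64-fold. Mature lymphocyte genes fell in 2 of 9 cases (camera adjusted p = 0.000177, 0.182 with an estimated correlation) and macrophage and mast cell genes in 1 of 16 (2 adjusted over the list alone, 0.000265, 0.182). DESeq2 called 190 genes, the fit with the Y-linked covariate 14 and the fit of all libraries 2 higher and 41 lower, and leaving out het 1, het 2, het 3, ko 1 or ko 3 left 45, 34, 38, 38 and 36. Klf1, Tslp, Wtap, Cdkn1b, Slc39a1 and Clnk lost their calls in 5 to 10 of 15 alternatives, among them leaving out any of 3 to 7 of the 8 libraries (up to 0.256, 0.36, 0.913, 0.324, 0.6 and 0.321), Mmrn1 without het 1 or ko 3 and Tnip3 without ko 3, both also by limma voom and with the Y-linked covariate (up to 0.216 and 0.225). Cpa3 and Il1r1 did not pass in the fit of all libraries, nor Dntt, Lck and Il1r1 with the Y-linked covariate (up to 0.211 for Cpa3, 0.0976 for Il1r1 and Dntt and 0.0863 for Lck). In GMP, Gpr141 fell 4.71-fold (-2.24 ± 0.25, adjusted p = 0.00197) and Il18rap 4.91-fold (0.0485), the second of these not without het 1, 2 or 4 or ko 1, 3 or 4 (up to 0.619 over all alternatives), with 538 genes at unadjusted p under 0.05 (604 by chance) and 40 called by DESeq2. Among GMP lists the HSC-associated genes rose again, with 0 of 17 past the test (6 adjusted over the list alone, 1.91e-06, 0.0346 with an estimated correlation).

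The change in ko against wt differed between populations for some of these genes. Mmrn1 fell further in HPC than in HSC (difference -3.88 ± 0.52, adjusted p = 1.46e-05) and in pGM than in HSC (-2.79 ± 0.54, 0.00639). The change was also lower than in HSC for Car2, which was not called in HSC (0.25), in HPC and pGM (difference -1.21 ± 0.23 and -1.29 ± 0.23, adjusted p 0.00308 and 0.00138), for Art4 (-3.00 ± 0.38, 7.36e-06) and Gata3 (-1.84 ± 0.42, 0.0385) in HPC, and for the lymphoid nuclear factor Tox (-2.59 ± 0.32, 3.61e-06) and Lck (-1.26 ± 0.29, 0.0444) in pGM. Fyb fell less in HPC (2.05 ± 0.28, 1.46e-05) and pGM (1.77 ± 0.28, 0.000254), and so did Cd53 in pGM (2.04 ± 0.30, 0.000146), while Ms4a6c, Tmem150b and Il18rap in HPC differed by 1.89, 2.26 and 2.26. In GMP the effects on Hoxa9 (1.16 ± 0.23, 0.00931), Gata2 (1.19 ± 0.27, 0.0254) and the MHC class II genes H2-Oa (1.22 ± 0.22, 0.00185) and H2-Ob (1.35 ± 0.27, 0.0105) were higher than in HSC. Those on Ptgir (-2.90) and Cd302 (-1.98) were lower. Of 15110 genes the change differed from HSC in 35 in HPC (24 higher, 11 lower), 33 in pGM (15 and 18) and 59 in GMP (47 and 12). In GMP against HSC, 2 of 14 MHC class II genes were higher (6 adjusted over the list alone, camera adjusted p = 0.000234, 0.247 with an estimated correlation). The calls of Gata3, Lck, Gata2 and Ptgir ended in 9 to 13 of 23 alternatives (up to 0.121, 0.154, 0.0717 and 0.0752), that of Il18rap without HPC ko 2 (0.0667), and 38 and 34 genes passed in GMP against HSC without HSC ko 1 and HSC wt 4. In pGM against HSC 19 to 21 passed without any of 9 of the 16 libraries, and 21 with no filter. DESeq2 called 60, 53 and 156, and limma voom 81 and 107 for pGM and GMP.

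**Figure D4:**
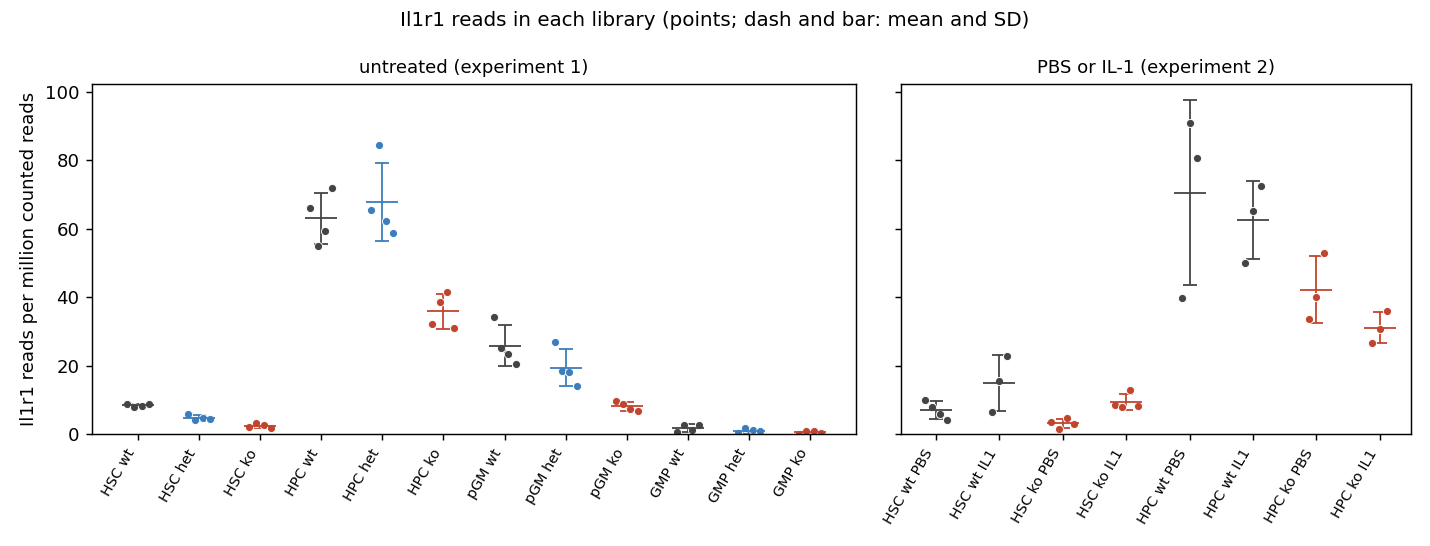
Il1r1 expression in CPM without TMM scaling (y axis), for each group of experiment 1 and of experiment 2 (x axis), with points for libraries, dashes for means and bars for SD. Means of untreated wt and ko were 8.42 and 2.49 in HSC, 63 and 35.9 in HPC and 25.8 and 8.14 in pGM.

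After PBS, ko and wt HSC differed in 132 genes, of which 81 were also called in untreated HSC. Gpx8 rose 15.8-fold to 10.8 ± 5.5 CPM (SD, n = 4 per group, 3.99 ± 0.64, adjusted p = 0.00516), the receptor partner Ramp2 7.43-fold to 12.8 ± 1.29, Armh4 4.7-fold, metallothionein Mt1 4.23-fold to 34.8 ± 11.6, Flrt3 3.87-fold and Gstm2 3.75-fold. Il18rap fell 16.8-fold from 19.9 ± 4.45 to 1.17 ± 0.599 CPM (-4.07 ± 0.46, adjusted p = 0.000332). Fam198b fell 37.4-fold, P2ry10 24.4-fold, Hdac9 13.7-fold, Rgs7bp 12.9-fold and Cd96 11.4-fold. Hemgn fell 3.37-fold to 14 ± 1.53 CPM and Bgn 3.2-fold to 36 ± 5.8 (0.00283 and 0.00871). Platelet genes fell in 2 of 22 cases (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 1.09e-05, 0.121 with an estimated correlation), Gp1ba 3.37-fold and F2rl2 2.48-fold. Macrophage and mast cell genes fell in 2 of 13 (10 adjusted over the list alone, 2.06e-10, 0.121), among them Cd163 by 2.07-fold, and stroma genes in 2 of 13 (3 adjusted over the list alone, 5.57e-05, 0.203), with Vcam1 4.4-fold lower. Without HSC wt IL1 replicate 1, which shares the fit, the estimated-correlation p was 0.00616, 0.00109 and 0.0917 for these lists in turn. In all, 39 genes were higher and 93 lower of 16538. DESeq2 called 154 and 220, no filter gave 246 and the Y-linked covariate 62, and the count was 49, 42 and 60 without ko 1, 2 or 3 and 60, 54, 74 and 61 without wt 1, 2, 3 or 4. The calls of Armh4, Gstm2, Cd163 and Flrt3 and of F2rl2 ended in 8 to 11 of 15 alternatives (up to 0.167, 0.223, 0.104, 0.119 and 0.145), Fam198b without ko 2 or ko 4 (up to 0.181 over all alternatives), Vcam1 without ko 2, ko 3, ko 4 or wt 1 (0.0972), and P2ry10 with the replicate block and by limma voom (up to 0.279).

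After IL-1, edgeR called 0 genes between ko and wt HSC with all 7 libraries, with 1412 at unadjusted p under 0.05 (827 by chance). DESeq2 called 94, limma voom 362, the replicate block 190, the fit of all libraries 23 and no filter 43. Without HSC wt IL1 replicate 1, 159 genes passed, 34 higher and 125 lower, 61 of them also called after PBS. Kmt2c stood at 15.3 CPM in ko and 34.1 in wt with it (-1.16 ± 0.32, adjusted p = 0.279) and at 15.3 and 43.8 without it (-1.52 ± 0.26, 0.0066). Without it the largest rises were in Evc (log2 3.65), Map1b (3.27), Aebp1 (3.13), Armh4 (2.65), Fkbp10 (2.62) and Fez1 (2.47), with adjusted p of 0.00179 to 0.0145. The largest falls were in the mucin Muc2 (-6.14), Gprin3 (-4.41), Hdac9 (-3.89), Plscr2 (-3.75), the lectin Clec4e (-3.67, adjusted p = 5.63e-06) and the ammonium transporter Rhag (-3.64), with adjusted p of 0.0299 or less. Macrophage and mast cell genes (camera adjusted p = 3.45e-10, 0.00427 with an estimated correlation), platelet genes (2.68e-05, 0.0157), mature neutrophil genes (0.000359, 0.0444) and lymphoid-primed genes (0.000254, 0.0444) fell as lists without it, and so did mitochondrially encoded (4.72e-10, 0.229) and cytosolic ribosomal protein genes (3.01e-12, 0.383).

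In wt HSC given IL-1, Wfdc17, a small secreted antiprotease, rose 20.9-fold from 5.06 ± 1.06 to 106 ± 25.8 CPM (SD, n = 4 PBS and 3 IL-1, 4.39 ± 0.39, adjusted p = 1.81e-05; without the library labelled HSC wt IL1 replicate 1, 4.57). The receptor Gpr18 rose 10.1-fold, the beta globin gene Hbb-bt 8.95-fold to 556 ± 39.7 CPM, the granulocyte precursor gene Ms4a3 8.55-fold, the mucin Muc1 6.35-fold and Wfdc18 6.16-fold. Without that library Gpr18, Ms4a3 and Hbb-bt changed by 3.74, 3.50 and 3.16 log2 units. Selp rose 3.83-fold to 71.9 ± 12.7 CPM, Gata1 2.93-fold to 62.3 ± 6.74 and cathepsin Ctss 3.02-fold to 91.6 ± 11.3. The chemokine Cx3cl1 fell 5.55-fold (-2.47, and -2.62 without that library), cyclin D2 (Ccnd2) from 757 ± 24 to 312 ± 111 CPM (-1.28 and -1.62), the channel Trpc6 2.47-fold and Lhcgr 2.26-fold. Of 22 cholesterol synthesis genes 0 passed (9 lower adjusted over the list alone, camera adjusted p = 2.19e-12, 0.297 with an estimated correlation), and ribosome biogenesis genes fell by camera (6.18e-13, 0.297). Without that library these were 6.97e-12 and 0.168, and 6.66e-21 and 0.0616, and mitochondrially encoded and cytosolic ribosomal protein genes rose (2.61e-07, 0.381, and 1.46e-12, 0.513). Granulocyte-monocyte genes had 1 of 29 higher (3 higher and 1 lower adjusted over the list alone, 0.0184, 0.297), and without that library the list had 0.000902 and 0.0519.

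IL-1 changed 33 of 16538 genes in wt HSC, 26 higher and 7 lower. Without HSC wt IL1 replicate 1 it was 38, of which 23 were shared. DESeq2 called 178, limma voom 243, no filter gave 91 and the replicate block 167. Leaving out IL1 2, IL1 3, PBS 1, PBS 2 or PBS 4 left 9, 17, 17, 16 and 16. The calls of Muc1, Wfdc18, Trpc6, Lhcgr, Gata1 and Ccnd2 ended without any of 5 to 7 of the 7 libraries (up to 0.127, 0.171, 0.151, 0.419, 0.151 and 0.228 over all alternatives). Those of Cx3cl1, Selp and Ctss ended without IL1 2 or IL1 3 (and Selp without PBS 4, Ctss without PBS 1 or 2), up to 0.0721, 0.0721 and 0.072 over all alternatives, and that of Ms4a3 without IL1 2 (0.0873).

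In ko HSC, IL-1 raised Selp as well, 3.72-fold to 59.9 ± 8.87 CPM (SD, n = 4 per group, 1.90 ± 0.29, adjusted p = 0.00663), with F2rl2 4.44-fold, Gata1 2.65-fold and Gpr18 5.37-fold higher. Cd53, a leukocyte tetraspanin, rose 8.66-fold from 12.7 ± 6.39 to 110 ± 29.3 CPM (3.11 ± 0.42, 0.00205), Il18rap 7.21-fold, Tgfbi 6.1-fold and the iron-binding neutrophil protein Lcn2 56.7-fold from 0.155 ± 0.122 to 8.81 ± 13.6. Ccnd2 fell 2.34-fold from 1060 ± 127 CPM (-1.23 ± 0.22, 0.0194), cyclin D1 (Ccnd1) 2.91-fold, and the retinoic acid hydroxylase Cyp26b1 6.85-fold. Platelet genes had 2 of 22 higher (5 adjusted over the list alone, camera adjusted p = 0.027, 0.616 with an estimated correlation). Mitosis genes had 0 of 30 past the test (5 higher adjusted over the list alone, 5.7e-16, 0.487), and cholesterol synthesis genes fell (6 lower adjusted over the list alone, 1.58e-10, 0.487). Without HSC wt IL1 replicate 1 the estimated-correlation p was 0.341, 0.347 and 0.347. In all, 24 genes were higher and 11 lower. DESeq2 called 180, no filter gave 100, the replicate block 71 and limma voom 58, and leaving out IL1 1, 2, 3 or 4 or PBS 1 or 2 left 22, 22, 18, 22, 22 and 9. The calls of Lcn2, Gpr18, Cyp26b1, Ccnd1 and Gata1 ended without any of 4 to 7 of the 8 libraries (up to 0.304, 0.239, 0.142, 0.164 and 0.177 over all alternatives), Ccnd2 without IL1 3, IL1 4 or PBS 2 (0.0916), Tgfbi without PBS 2 or PBS 4 (0.0659) and Il18rap without PBS 2 (0.0626).

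EdgeR called no gene's IL-1 response different between ko and wt HSC, with or without HSC wt IL1 replicate 1. With it, 756 had unadjusted p under 0.05 (827 by chance). By camera 4 lists were higher and 3 lower, the HSC and HPC sets lower (0.0189 and 0.0349) and the pGM set higher (0.0189), none with an estimated correlation. Without that library DNA replication (1.49e-09) and mitosis genes (3.9e-06) were among those higher and mitochondrially encoded (1.24e-08) and ribosomal protein genes (2.88e-22) among those lower. DESeq2 called 1 and the replicate block 20. Simulated differences of 4-fold and 2-fold were recovered for 82 and 7 of 100 genes. The estimate for Kmt2c was 0.39 ± 0.43 (adjusted p = 0.876), and 0.03 ± 0.35 (0.992) without that library.

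In wt HPC given IL-1, 7 of 30 granulocyte-monocyte genes rose (13 adjusted over the list alone, camera adjusted p = 2.17e-13, 0.0261 with an estimated correlation, and 1.03e-12 and 0.0051 with the replicate block). The inhibitory Fc receptor Fcgr2b rose 5.86-fold to 57.2 ± 16.9 CPM (SD, n = 3 per group, 2.55 ± 0.23, adjusted p = 0.000151), Igsf6 10.2-fold, Ly86 7.48-fold to 83.2 ± 11, Ms4a3 5.71-fold and Csf1r 2.86-fold to 86.1 ± 6.68. By size, Mrgpra2a and Mrgpra2b rose 38.5-fold and 36.5-fold, Tlr1, a receptor for bacterial lipopeptides, 19.4-fold, Ehd3 15.9-fold to 34.1 ± 4.15 CPM, Olfm1 14.9-fold and the chemokine Ccl5 14.1-fold to 123 ± 47.2. The stress gene Ddit4l fell 17.4-fold, the B cell factor Ebf1 7.78-fold, Trib2 6.73-fold, Trpc6 6.4-fold and Mycn 6.17-fold from 49.4 ± 14.3 CPM (-2.62 ± 0.31, 0.000622). Of 14 MHC class II genes 2 rose, Ctss 2.42-fold to 253 ± 12.4 CPM and Cd74 3.26-fold (3 higher and 1 lower adjusted over the list alone, 9.83e-05, 0.207 with an estimated correlation, and 0.000306 and 0.369 with the block). Ly6a rose 2.38-fold, Cd22 8.89-fold, Klrd1 4.02-fold and Hbb-bt 4.53-fold, and Ccr9 fell 6.05-fold. HSC-associated genes fell in 2 of 30 cases (6 lower and 1 higher adjusted over the list alone, 6.39e-05, 0.556, and 8.25e-05 and 0.376 with the block), among them Hlf by 2.06-fold. Mitochondrially encoded (0.000212, 0.859, block 0.000406) and stroma genes (0.0367, 0.219, 0.0294) fell and mature lymphocyte genes rose (0.0367, 0.219, 0.0537).

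Of 15951 genes in wt HPC, 112 were higher and 39 lower after IL-1, and 315 passed with the replicate block. DESeq2 gave 278 and 190, limma voom 183 and 116, the fit of all libraries 77 and 69, and no filter 261 in all. Without IL1 2, IL1 3 or PBS 2 the count was 95, 95 and 69. The calls of Tlr1, Ebf1, Olfm1, Klrd1, Hlf and Ccr9 ended without any of 3 to 6 of the 6 libraries (up to 0.258, 0.242, 0.181, 0.103, 0.0829 and 0.0943 over all alternatives). Without PBS 2, Mrgpra2a, Cd22, Cd74, Ly6a and Csf1r did not pass, nor did Cd22, Cd74 and Ly6a without PBS 3 and Csf1r without PBS 1 (up to 0.0692, 0.104, 0.0767, 0.0879 and 0.381 over all alternatives).

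In ko HPC, IL-1 raised Mrgpra2a 39.3-fold, Ehd3 11.4-fold to 13.3 ± 0.585 CPM (SD, n = 3 per group, 3.51 ± 0.49, adjusted p = 0.00443), the inhibitory receptor Pdcd1 11.2-fold, Nsg2 11.1-fold, Il31ra 9.18-fold, Ly86 6.79-fold to 58.9 ± 15.8, Fcgr2b 2.92-fold, Hbb-bt 3.5-fold and Ctss 1.93-fold. Ddit4l fell 17.9-fold, Cd209f 25.2-fold, the lysophosphatidic acid receptor Lpar1 7.16-fold, Ccr9 5.79-fold, Jchain 5.06-fold from 573 ± 236 CPM, Eya2 3.82-fold and Mycn 3.42-fold. The granulocyte-monocyte list had 2 of 30 higher (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000501, 0.572 with an estimated correlation, and 0.000508 and 0.259 with the replicate block), and the HSC-associated list 1 lower (7 lower and 1 higher adjusted over the list alone, 7.9e-08, 0.572, and 1.57e-07 and 0.419 with the block). In all, 47 genes were higher and 22 lower, and 132 passed with the replicate block (76 and 56). DESeq2 called 233, limma voom 187, no filter gave 134 and the fit of all libraries 30 higher and 28 lower, and without IL1 2, IL1 3, PBS 1 or PBS 2 the count was 37, 41, 31 and 28. The calls of Pdcd1, Il31ra, Cd209f, Ccr9, Jchain, Ctss, Eya2 and Mycn ended without any of 3 to 5 of the 6 libraries (up to 0.272, 0.124, 0.197, 0.16, 0.164, 0.162, 0.0587 and 0.112 over all alternatives), those of Mrgpra2a and Fcgr2b without PBS 1 or PBS 2 (up to 0.131 and 0.0568) and that of Hbb-bt without PBS 2 (0.0633).

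No gene's IL-1 response was called different between ko and wt HPC by edgeR (0, also with the replicate block, with 352 at unadjusted p under 0.05, 798 by chance), and DESeq2 called 12. Simulated differences of 4-fold were recovered for 66 of 100 genes and of 2-fold for 11. The granulocyte-monocyte list rose less in ko than in wt, with a median difference of -0.46 and 0 of 30 members called (camera adjusted p = 1.33e-08, 0.111 with an estimated correlation, and 3.02e-09 and 0.0205 with the replicate block). MHC class II genes did so too (9.18e-06, 0.114, and 1.82e-05 and 0.284 with the block). Cholesterol synthesis, glycolysis and macrophage and mast cell genes also differed downward (0.0459, 0.0358 and 0.0358, each 0.866), and mitochondrially encoded genes upward (7.63e-06, 0.866, and 2.52e-05 with the block).

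In ko HPC of experiment 2 against wt after PBS, P2ry10 fell 11.2-fold to 1.52 ± 0.369 CPM (SD, n = 3 per group, -3.49 ± 0.41, adjusted p = 0.00468), Gdf3 8.57-fold, Mmrn1 8.28-fold from 35.2 ± 17.9, Trpc6 6.39-fold, S1pr1 6.31-fold, Cd96 5.54-fold and Hemgn 2.73-fold. Slc6a15 rose 6.39-fold, Igsf6 4.41-fold, Tcaf1 4.22-fold and Serpinh1 3.97-fold to 40.9 ± 12.5. After IL-1, Cd96 fell 10.5-fold from 67.8 ± 28.2 CPM, Mmrn1 9.69-fold, Clnk 8.65-fold, P2ry10 5.95-fold, Eya2 5.86-fold to 7.17 ± 2.9 (-2.55 ± 0.30, 0.00394), S1pr1 5.78-fold, Hemgn 3.49-fold and Trpc6 4.94-fold, while the synaptic gene Cplx2 rose 6.49-fold, the syndecan Sdc2 3.86-fold and Nsg1 2.62-fold. After PBS the granulocyte-monocyte list was higher with 1 of 30 members called (3 adjusted over the list alone, camera adjusted p = 3.09e-05, 0.394 with an estimated correlation, and 1.01e-05 and 0.0866 with the replicate block), and mitochondrially encoded genes were lower (3.09e-05, 0.891, and 7.78e-05 with the block). After IL-1 the platelet list was lower with 1 of 21 members called (9.54e-06, 0.347, and 3.07e-06 and 0.362 with the block), and mitosis genes were higher with 0 called (9.72e-07, 0.717, and 5.7e-07 and 0.626 with the block).

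After PBS 14 genes were higher and 27 lower in ko HPC, and 95 passed with the replicate block. After IL-1 it was 8 and 24, and 65 with the block. DESeq2 called 233 and 157, no filter gave 123 and 93, the Y-linked covariate 20 and 12, the fit of all libraries 65 after PBS and 23 higher and 25 lower after IL-1, and limma voom 174 after IL-1. Leaving out any of the 6 PBS libraries left 7 to 17 genes, with 7 without wt 2 or wt 3. After IL-1, leaving out ko 1, 2 or 3 or wt 1, 2 or 3 left 16, 2, 18, 58, 9 and 10. After PBS, P2ry10 and S1pr1 held in each alternative and Trpc6 in all but leaving out wt 3 (adjusted p = 0.0549), and the others named lost their call without any of 5 or 6 of the 6 libraries (up to 0.316 over all alternatives). After IL-1, each of the genes named lost its call without ko 2 (0.0508 or more), and P2ry10, Hemgn, Trpc6, Cplx2, Sdc2 and Nsg1 also without other libraries (up to 0.163, 0.127, 0.159, 0.214, 0.19 and 0.159 over all alternatives).

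The IL-1 response of wt HPC differed from that of wt HSC in 4 of 17511 genes, named after their values were seen. Ehd3 (3.21 ± 0.52, adjusted p = 0.0112) and Unc93b1 (1.45 ± 0.24, 0.0161), which carries Toll-like receptors to endosomes, responded more in HPC, and Wfdc17 (-4.64 ± 0.49, 1.05e-05) and Wfdc18 (-3.57 ± 0.65, 0.0407) responded less. Without HSC wt IL1 replicate 1, Wfdc17 alone passed (-4.81, 8.37e-06). Ehd3 also lost its call without HPC wt PBS 2 or HSC wt IL1 2 (up to 0.0873), and Unc93b1 and Wfdc18 lost theirs in 8 and 13 of 19 alternatives (up to 0.149 and 0.198). DESeq2 called 20, the replicate block gave 33 and limma voom 17.

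Genes marking populations of experiment 1 were then tested as sets in experiment 2. The HPC set is led by immunoglobulin and T cell receptor genes, so its shifts need not be those of progenitors. In wt HPC, IL-1 raised the set of 161 GMP genes (median log2 change 0.45, 15 higher and 0 lower, camera adjusted p = 6.25e-07, 0.0833 with an estimated correlation). This rise was smaller in ko HPC (median difference -0.29, 0.000441, 0.501). In wt HSC, IL-1 raised the HPC set (median 0.24, 1.33e-05, 0.207, and 0.0309 with an estimated correlation without the library labelled HSC wt IL1 replicate 1). In ko HSC it lowered the HSC set (median -0.39, 5.57e-09, 0.0703) and raised the pGM set (0.32, 4.01e-07, 0.0817). After PBS, ko HSC were higher than wt in the HSC set (median 0.33) and lower in the HPC set (-0.11), both with 0.000232 and 0.182. After IL-1, ko HSC were lower than wt in the HPC set (median -0.38, 2.3e-11, 0.0952), and without that library the values were 3.12e-13 and 0.0223. Of 44 tests 26 passed with the preset correlation and 0 with an estimated one.

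Changes in ko against wt were compared between the experiments, which have their own wt and ko libraries. Across 13712 genes, which are not independent replicates, the log2 changes of untreated HSC and HSC after PBS had a Pearson r of 0.51 (jackknife SE 0.08, Spearman rho 0.28). Of the 246 genes called in untreated HSC, 243 had the same sign after PBS. Both experiments called 81 genes, 13 higher and 68 lower, where 0.219 and 1.12 would share a direction by chance. In HPC r was 0.44 (SE 0.09, rho 0.25) across 13162 genes, 0.33 without HPC wt PBS replicate 3, 143 of 146 genes had the same sign, and 22 were called in both, 4 higher and 18 lower (0.0326 and 0.232 by chance). Within 10 Mb of Kmt2c genes were not called more often than others in untreated ko cells, with 3 of 142 genes in HSC, 0 of 134 in HPC, 3 of 128 in pGM and 1 of 113 in GMP (Fisher's exact test, 2-sided, p = 0.743, 0.408, 0.74 and 0.464). Within 20 Mb they were in HSC, with 8 of 201 near Kmt2c, 3.98% against 1.75% elsewhere (Fisher's exact p = 0.0279).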

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

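The tests of HSC wt IL1 replicate 1, Sva and the GMP libraries in this part were chosen after the results were seen. Of 57 tests for a library far from its group, each on 1 measure, 7 found one, and chance gives about 1 in 20. The total of pGM ko 3 (20.3 M reads) and the share of mitochondrially encoded reads in GMP wt 4 (0.482%) stood apart. Sva reads stood apart in HPC het 2 with 41, HPC ko 2 with 49, HPC wt 4 with 1, HSC het 1 with 31 and pGM wt 2 with 3. The other HPC wt and pGM wt libraries held 0, so any read stands apart there and 1 in 20 does not apply. Library pGM het 1 held 266 reads on a human gene ID, repeated in a human fusion entry. Wt libraries held at most 4 and the others at most 11. By test of the difference, the ko change differed from HSC in 35 genes in HPC, 33 in pGM and 59 in GMP. The IL-1 response of wt cells differed between HPC and HSC in 4 genes.

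The library labelled HSC wt IL1 replicate 1 had Kmt2c at the level of ko libraries. A swap with a ko IL1 library would leave one of those among the wt libraries, but the lowest of them lay at 0.76 on the axis from wt to ko. A mixture in comparable shares is argued against by the median ko share of 0.961 over 67 genes at least 2-fold lower in ko (quartiles 0.889 and 1.05). Its position of 0.85, inside the range of 0.76 to 0.88 of the ko IL1 libraries, is what a single wrong label may give, and its 59 Sva reads are in line with a Vav-Cre library. This remains a hypothesis found and tested on the same data, and no other biological explanation was tested.

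Sva was read in all 46 libraries labelled Vav-Cre and nearly absent from wt ones other than HSC wt IL1 replicate 1. A response that scales with the loss of Kmt2c is argued against, since the median ko against het change over 4 populations was 0.07 (0.58 with 2 SE added), whereas the share of Kmt2c lost was larger in ko than in het by 0.88 to 1.69 log2 units. A strain region carried with the Cre transgene may still be the source, since 1 of the few tested genes within 1 Mb was called in ko against wt, in GMP, and 9, 13, 12 and 7 genes are too few to decide. Sequence in the transgene itself was not tested.

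The libraries GMP het 1 and GMP ko 2 stood apart from their groups, with an SD over 7284 genes of 0.63 and 0.61 in the difference from the group, against 0.26 to 0.39 in the others. Depth is argued against, since after thinning all to 13.3 M reads the highest of the others stayed at 0.39. A lower yield of long transcripts may contribute, since the difference correlated with exon length across genes at -0.29 and -0.36 (Spearman), but other GMP libraries ranged from -0.43 to 0.38, so this cannot be told apart from the spread between libraries. Mitochondrially encoded genes were higher in both, by 1.44 and 1.51 log2 units, against -1.87 to 0.46 in the others. Whether a biological difference between animals is the source was not tested.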

How the results depend on the processing

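Chosen after the data were seen were the Y-linked covariate and the fits without GMP het 1 and GMP ko 2. So were the block of genotype and number and the list tests without HSC wt IL1 replicate 1. The others were set before. Of 366 results for single genes, DESeq2 kept the direction and the call of 366, RLE scaling of 364, no filter of 337, the replicate block of 325, limma voom of 334 and the Y-linked covariate of 256, and 1 fit of all libraries of an experiment of 214 of 294. Leaving out 1 library ended 769 of 3047, without the 2 GMP libraries 2 of 24 ended, and with genotype and number as a block 2 of 68. Where more or fewer genes passed, the cause was not tested, except that leaving out a library leaves fewer samples.

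Results that turned direction were uncalled differences in the Kmt2c effect. HPC minus HSC was 0.06 by limma voom and 0.03, 0.03, 0.16, 0.01, 0.03 and 0.06 with 1 library left out (all left-out fits -0.15 to 0.16). It was 0.08 for pGM minus HSC without pGM ko 4 (-0.26 to 0.08). For GMP minus HSC it was -0.18 by limma voom and -0.11 without GMP ko 2 (left-out fits -0.11 to 0.39), and for the IL-1 response of HPC between genotypes 0.12 without HPC wt PBS 1 (-0.39 to 0.12).

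These counts of called genes moved by more than 1.5 times. By DESeq2, ko against wt, het against wt and ko against het gave 469, 20 and 136 in HSC, 302, 13 and 111 in HPC, 421, 58 and 190 in pGM, and 225 and 40 for the first and last in GMP. Differences from HSC in the ko effect were 60, 53 and 156 for HPC, pGM and GMP. In experiment 2, DESeq2 gave 178 and 180 for IL-1 in wt and ko HSC, 374 and 94 for ko after PBS and IL-1 and 1 for the genotype difference. In HPC these were 468, 233, 233, 157 and 12, and the IL-1 difference between populations was 20. RLE scaling gave 1 in GMP ko against het. No filter on low counts gave 9 in GMP ko against het, 21 for pGM minus HSC, 91 and 100 for IL-1 in wt and ko HSC, 246 and 43 for ko after PBS and IL-1 and 1 for the genotype difference, and 261, 134, 123 and 93 for the first 4 of these in HPC.

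With the replicate block, HSC and GMP het against wt gave 0 and 0, pGM het against wt 7, HPC ko against het 13, GMP ko against wt 43 and ko against het 1, and wt HPC against HSC 1352. In experiment 2 the replicate block gave 167 and 71 for IL-1 in wt and ko HSC, 190 for ko after IL-1 and 20 for the genotype difference, 315, 132, 95 and 65 for the HPC comparisons, and 33 for the IL-1 difference between populations. Limma voom gave 448, 286 and 229 for ko against wt in HSC, HPC and GMP, 4 and 2 for het against wt in HSC and HPC, 10 for GMP ko against het, 81 and 107 for pGM and GMP minus HSC, 243, 58 and 362 for IL-1 in wt and ko HSC and ko after IL-1, 299, 187 and 174 for the same in HPC, and 17 for the IL-1 difference between populations.

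The Y-linked covariate gave 36, 128 and 12 for ko against wt in HPC, pGM and GMP, 2 for het against wt in HSC, and 22, 2, 14 and 0 for ko against het in HSC, HPC, pGM and GMP. In experiment 2 it gave 62 for ko HSC after PBS and 1 for the genotype difference, and 20 and 12 for ko HPC after PBS and IL-1. In 1 fit of all libraries, GMP ko against wt gave 197, pGM and GMP het against wt 1 and 5, ko against het 46, 43 and 26 in HPC, pGM and GMP, ko HSC after IL-1 23, the HSC genotype difference 1 and ko HPC after PBS 65. Without the libraries GMP het 1 and GMP ko 2, GMP ko against wt gave 194 and ko against het 8.

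With 1 library left out, counts ranged from 151 to 233 in HSC, 80 to 99 in HPC, 160 to 232 in pGM and 16 to 66 in GMP for ko against wt. For het against wt they ranged from 1 to 4, 0 to 2, 0 to 6 and 0 to 0, and for ko against het from 29 to 58, 11 to 33, 34 to 107 and 1 to 6. Differences in the ko effect ranged from 25 to 40 for HPC, 19 to 33 for pGM and 34 to 75 for GMP. For IL-1 in wt and ko HSC the ranges were 9 to 38 and 9 to 35, for ko HSC after PBS and IL-1 42 to 91 and 0 to 159, for IL-1 in wt and ko HPC 69 to 145 and 28 to 86, for ko HPC after PBS and IL-1 7 to 17 and 2 to 58, and for the IL-1 difference between populations 1 to 4.

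Of 783 list tests 259 passed at the preset correlation, 26 with an estimated one and 80 by fry, which does not compare a list with the other genes, and 248 to 274 with 1 library left out. Of 44 tests of population sets 26 passed and 0 with an estimated correlation. The correlation of the ko effect across experiments was 0.81 in HSC and 0.86 in HPC over called genes alone, and 0.33 to 0.45 in HPC and 0.45 to 0.53 in HSC with 1 library left out. At 10 CPM or more, the excess covariance of het and ko effects was 0.0117 in HSC and 0.00835 in pGM. With 1 het or ko library left out it ranged from 0.0475 to 0.066 in HSC, 0.0388 to 0.0682 in HPC, 0.0286 to 0.0487 in pGM and 0.0196 to 0.0575 in GMP. The Fisher's exact p near Kmt2c in HSC was 0.0279 at 20 Mb.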

Other observations

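The set test in GMP was chosen after the results were seen, the sample splits before.

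A hypothesis is that ko GMP keep features of earlier cells. Against het GMP, which also carry Vav-Cre, 200 genes that mark wt GMP were lower by -0.29 log2 units. Of 200 that mark wt HSC, the 12 past the filter, near the floor (0.74 log2 CPM in ko, 0.12 in het), were higher by 0.62. Both had p = 0.0286 (exact permutation test, 2-sided, 4 against 4), the smallest possible, adjusted 0.0572 over 4 sets. The HPC and pGM sets differed by -0.14 and 0.08 (exact p = 0.0857 and 0.114). None passed after adjustment, so the values stay open, and the filter or the composition of the sort may equally give a shift.

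Other splits of the same libraries were fitted to see whether chance can give as many genes. For ko against wt, 1 of 35 splits, the real one, gave as many in HSC (246, highest other 0), HPC (146, other 1), pGM (251, other 3) and GMP (67, other 1), so chance, though not sex, can be excluded. For het against wt, 2 of 35 gave as many in HSC (1, other 56), HPC (1, other 1), pGM (2, other 86) and GMP (1, other 1), so by the count alone it cannot. For Sva, called in each, the reads in all 46 Vav-Cre libraries of both experiments argue against chance. The splits with 56 and 86 point to a structure of the samples. For ko against het it can be excluded in HSC (1 split, 45, other 2) and pGM (1 split, 73, other 23) and not in HPC (2 splits, 26, other 1452) and GMP (2 splits, 2, other 32). The HPC split with 1452 genes puts ko 1 and ko 4 with het 3 and het 4, and the GMP one ko 1, 2 and 4 with het 1, both of which point to a structure of the samples. For differences in the ko effect from HSC, 3 of 60 splits in HPC (35, other 91), 2 in pGM (33, other 273) and 1 in GMP (59, other 36) gave as many. Chance can be excluded for GMP and not for HPC or pGM, where the split with 273 genes points to a structure of the samples. Between wt populations chance can be excluded, with 1 of 35 splits each (HPC 3440, other 36, pGM 6252, other 4, and GMP 9250, other 1711).

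In experiment 2 chance can be excluded for IL-1 in ko HSC (1 of 35 splits, 35, other 1). From the count alone it cannot be for IL-1 in wt HSC (2 of 35, 33, other 61) nor for ko against wt HSC after PBS (2 of 35, 132, other 317), although 81 of those 132 genes were also called in untreated HSC, each in the same direction. The split with 317 genes puts ko PBS 1 and 3 with wt PBS 1 and 2 and points to a structure of the samples. For ko against wt HSC after IL-1, 35 of 35 splits gave at least the 0 of the real one (other 32), and for the genotype difference in the IL-1 response 100 of 100 in HSC (0, other 12) and 100 of 100 in HPC (0, other 34). The 10 splits in HPC are too few for a share under 0.05. The real value and the highest other were 151 and 0 for IL-1 in wt, 69 and 0 in ko, 41 and 0 for ko after PBS, and 32 and 1 for ko after IL-1, each matched by 1 split. The IL-1 difference between HPC and HSC was matched by 6 of 60 (4, other 14), so chance cannot be excluded.

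The ko effect's correlation across experiments was matched by 1 of 100 splits in HSC (0.51, highest other 0.33) and HPC (0.44, other 0.29). Chance, though not Vav-Cre or in HSC sex, can thus be excluded. It cannot be for the number of list tests (9 of 40, 259, other 283, median of the others 233), for that of population sets (2 of 40, 26, other 26), nor for the excess covariance of het and ko effects in HSC (6 of 60, 0.0576, other 0.134), HPC (4 of 60, 0.0526, other 0.12), pGM (5 of 60, 0.0356, other 0.0523) and GMP (8 of 60, 0.0473, other 0.117). For calls near Kmt2c, 1 of 35 splits per population had a p as small as the real one. Splits with almost no calls have a p of 1, so this decides nothing.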
